A study of Homo sapiens with 4 samples.

How the data were processed

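RNA was sequenced from MiaPaCa cells, an established human pancreatic cancer cell line. The cells stably carried 1 of 2 variants of SRP9, a small protein of the signal recognition particle that binds the Alu domain of the particle's RNA. Each variant was fused to a FLAG tag and a nuclear localisation signal, and transfected cells were selected with Geneticin and sorted by a fluorescent reporter, per the labels' protocols. For each variant, 1 library was made from RNA co-precipitated with the tagged protein (RNA immunoprecipitation, RIP) and 1 from the whole-cell RNA of the same experiment (input). The 4 libraries thus form 4 groups of 1 library each. No library from a precipitation without a tagged SRP9 was analysed here.

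Per the submitters' processing notes, the tools named are HISAT2 2.1.0 and featureCounts from Subread 2.0.0, with the genome build GRCh38.p13. The annotation release, the strand setting and the treatment of multi-mapping and overlapping reads are not given in the sources used here. The deposited values are estimated counts of reads per Ensembl gene ID, not normalized by the authors as far as the column names and the differing totals show. Each library lists 60676 IDs. Between 13.9% and 18.0% of a library's values hold a fraction of a read, as arises when 1 read is divided between several genes or positions. Among the 27963 IDs with a summed count over 100, 613 have the same values as another ID in all 4 libraries, so such IDs are not independent measurements. Genes that overlap or have near-identical copies can have exchanged reads.

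The files give Ensembl IDs without gene names. The reference gene table used here (59792 genes) pairs 0 of its genes with an Ensembl ID, so no ID could be matched to a gene name, gene class, length or genome position. Names were not assigned from memory. The 33 gene lists fixed before the data were examined, the level of the transfected gene, the composition by gene class, and scaling on protein-coding genes were therefore not computed. The lists covered the signal recognition particle and its RNA, other small RNAs, nuclear RNAs, ribosomal and mitochondrial genes, amino acid and stress responses, secretion, cell cycle, and markers of other cell types. Whether the transfected gene bears out the library labels was not checked for the same reason.

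Values were rounded to whole counts. RIP was compared with input over both constructs with the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3), after TMM scaling and edgeR's expression filter by fraction (minimum count 10 at the median library size), which kept 41622 IDs. The cutoff applies as a CPM, so it is under 10 counts in the shallower RIP libraries and above 10 in the inputs. IDs seen only in RIP thus pass at lower counts than IDs seen only in the inputs. The 2 constructs served as 2 samples of each fraction, so a difference between constructs counts as error and the fit has 2 residual degrees of freedom. They are different constructs, not replicates, and the p-values measure the spread between these libraries. An ID was called at a Benjamini-Hochberg adjusted p under 0.05. The labels tie each RIP library to the input of the same transfected cells, and a fit with the construct as a block (1 residual degree of freedom) was the paired alternative. Across tested IDs, the difference between the RIP libraries and the difference between the inputs had a correlation of -0.0045. Of these IDs, 12812 were at 0 in both inputs and cannot show pairing. Over the 22939 IDs with at least 50 counts in the higher library of each construct, the correlation was -0.051. No common deviation of paired libraries was thus seen, but this set is chosen on the higher of RIP and input. It also includes IDs at 0 in both inputs, so these values cannot show that pairing is absent.

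Comparisons between 2 single libraries have no test. They are given as log2 ratios of TMM-scaled CPM (counts relative to the library total) with a prior count of 2, with the number of IDs at least 2-fold apart. Folds quoted for single IDs are ratios of TMM-scaled CPM. A library at 0 counts was set to 3 counts, per library. The fold is then a lower bound for counting error only, under that scaling and if reads are counted singly. Intervals of CPM are exact Poisson intervals and those of shares exact Clopper-Pearson intervals, both at 95%. They cover counting error only, since reads from amplified libraries are not independent molecules. Total counts were 3921361 and 5211354 in the RIP libraries of variants 1 and 2, and 50454080 and 58815384 in their inputs. A floor of 3 counts corresponds to 0.765, 0.576, 0.0595 and 0.0510 CPM in that order. Whether both reads of a fragment were counted is not given in the sources used here. If they were, a 0 allows 6 reads (1.53, 1.15, 0.119 and 0.102 CPM), the lower bounds are 2 times lower and the Poisson intervals are too narrow. Bounds on library totals and with 6 reads were computed after seeing the data.

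The rule for single IDs was the largest positive and negative log2 fold change with at least 50 counts in both libraries of the higher fraction, or in the higher library for RIP variant 1 against RIP variant 2. This rule was fixed at the same time as the lists, with 10 named genes per direction. Without names, only the first 2 IDs per direction are given. Alternatives were DESeq2 size factors or library totals in place of TMM, other filters, the DESeq2 Wald test (DESeq2 1.42.0), limma-voom (limma 3.58.1), the construct block, leaving out each library, another prior count and thinning all libraries to the smallest total. A test on simulated data for the RIP against input comparison used 41622 IDs with the real library sizes and dispersions, 200 of them changed. Of the IDs changed 4-fold, 12% were called, and of those changed 16-fold, 45%. None was called with the wrong sign (0), and 3 unchanged IDs were called. All other IDs were unchanged and the changes were balanced in direction, so the simulation does not check calls that depend on the scaling. Far fewer IDs were changed than were called in the data (20595 higher and 6583 lower). The adjusted p is stricter with so few changes, so these shares and false calls do not carry over to the real comparison.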

Results

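The series profiled RNA bound by 2 variants of SRP9 directed to the nucleus of MiaPaCa pancreatic cancer cells, to examine what the variants do there. There was 1 RIP library and 1 input library per variant, without replicates. The RIP libraries held 3921361 counts for variant 1 and 5211354 for variant 2. The inputs held 50454080 and 58815384, so the deepest library had 15.0 times the counts of the shallowest. All values below are per Ensembl gene ID, because the IDs could not be matched to gene names.

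The counts of the RIP libraries were spread over many more genes than those of the inputs. A count was present for 44658 IDs (73.6% of those listed) in RIP variant 1 and 51589 (85.0%) in RIP variant 2, against 28372 (46.8%) and 26720 (44.0%) in the inputs of variants 1 and 2. After thinning to the smallest total, the RIP libraries detected 44416 and 50897 IDs and the inputs 23384 and 22319. The 1000 most abundant IDs of each library took 22.6% and 21.6% of the counts in the RIP libraries, and 53.5% and 53.0% in the inputs. The 10 most abundant IDs took more similar shares, with 5.57% and 5.47% in the RIP libraries and 7.05% and 6.93% in the inputs.

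**Figure D1:**
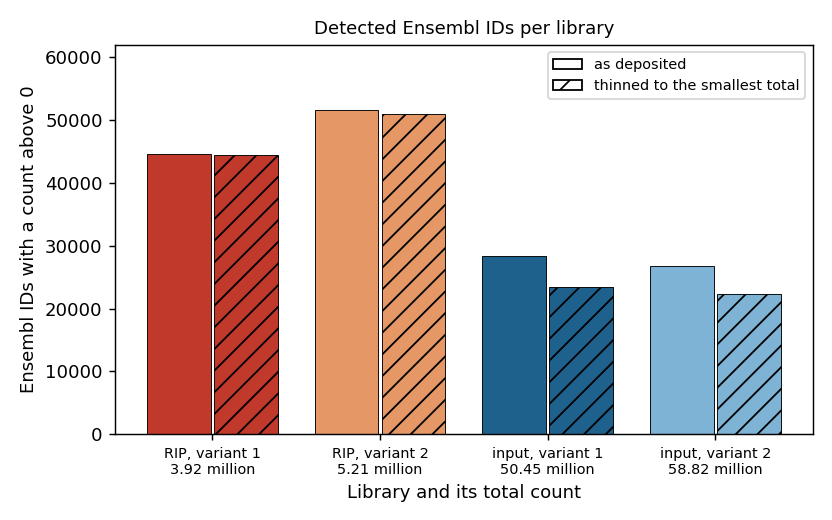
Number of Ensembl IDs with a count above 0 (vertical axis) in each of the 4 libraries (horizontal axis, with total counts), as deposited (plain bars) and after thinning to the smallest total (hatched bars); there is 1 library per group and no error bar. Both RIP libraries detect more IDs (44658 and 51589) than either input (28372 and 26720), although the inputs hold more counts.

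Genes without a count in the inputs made up a sizeable part of the RIP counts. Of all IDs, 28425 had 0 counts in both inputs. By counting error alone, a 0 allows a level of up to 0.0595 CPM in the input of variant 1 and 0.0510 CPM in that of variant 2. If each fragment was counted as 2 reads, it allows 0.119 and 0.102 CPM. These IDs took 15.0% of the counts in RIP variant 1 (95% exact binomial interval 15.0% to 15.1%) and 15.3% in RIP variant 2 (15.3% to 15.4%). A count was present in both RIP libraries for 14981 of them (52.7%), and in neither for 5483. At least 50 counts in both RIP libraries were present for 2593 of them. In the opposite direction, 96 IDs had at least 50 counts in both inputs and 0 in both RIP libraries.

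Median levels in the RIP libraries were above those in the inputs for IDs of low input abundance and below them for the most abundant, with IDs grouped by their summed input count. This grouping fixes the order of the inputs, so the same was read with IDs grouped on 1 library. Among the 93 IDs with a summed input count over 100000, the median was 265 CPM in RIP variant 1 and 262 CPM in RIP variant 2, against 1505 and 1442 CPM in the inputs. For the 5699 IDs with a summed input count from 1000 to 5000, the medians were close, with 24.4 and 24.7 CPM in the RIP libraries and 21.1 and 21.6 CPM in the inputs. For the 5191 IDs from 50 to 200, they were 7.91 and 9.08 CPM against 0.892 and 0.873 CPM. IDs at 0 in both inputs had medians of 1.02 and 1.92 CPM in the RIP libraries. Grouped on the input of variant 1 alone, the 7097 IDs over 1 and up to 10 CPM had medians of 2.86 CPM in the other input and 12.9 CPM in RIP variant 2, and the 90 IDs over 1000 CPM had 1591 and 284 CPM. Grouped on RIP variant 1 instead, the 18388 IDs over 1 and up to 10 CPM had medians of 4.61 CPM in RIP variant 2 and 0 in both inputs, the 1053 IDs over 100 and up to 1000 CPM had 111 CPM in RIP variant 2 and 87.3 CPM in the input of variant 2, and the 16 IDs above that had 2274 and 2303 CPM. The lower RIP level of the most abundant IDs was thus marked only with the groupings on inputs.

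**Figure D2:**
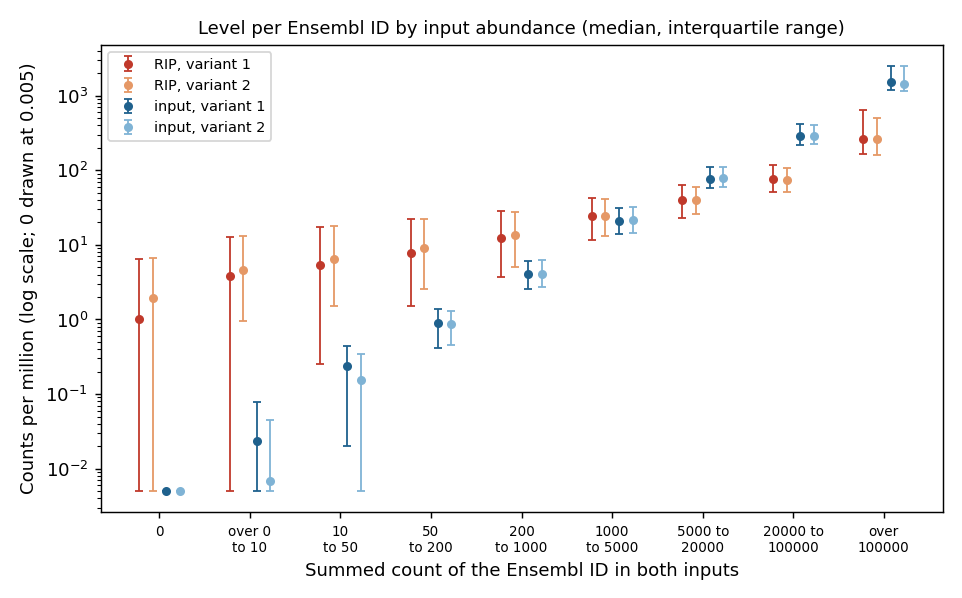
Median CPM (points, log axis, 0 drawn at 0.005) and interquartile range (bars) over Ensembl IDs grouped by their summed count in both inputs (horizontal axis), for the 4 libraries. The RIP medians lie above the inputs for low-abundance IDs (7.91 and 9.08 against 0.892 and 0.873 CPM at a summed count of 50 to 200) and below them for the most abundant (265 and 262 against 1505 and 1442 CPM).

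RIP was then compared with input over both constructs. Relative to TMM scaling, 20595 IDs were higher in RIP and 6583 lower among 41622 tested (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), so that 75.8% of the calls were higher. All 12812 tested IDs with 0 counts in both inputs were called higher, and they made up 12812 of the higher calls, with 7783 from IDs that had a count in an input. An ID at 0 in both inputs can only be equal or higher in RIP, so their direction is set by that choice. They also passed the filter through the RIP libraries alone, so whether they were tested depended on their RIP level. Some of these calls rest on few reads, as for ENSG00000235282 with 2 and 13 counts in RIP variants 1 and 2 (edgeR adjusted p = 0.022). With the construct as a block, 4526 of these IDs at 0 in the inputs were called, and 257 or 298 without RIP variant 1 or 2. The higher calls with a count in an input numbered 3763 with the block, 681 or 784 without RIP variant 1 or 2, and 4522 when IDs with a count in an input were fitted alone. Among the 15436 tested IDs with at least 50 counts in both inputs, 1282 were higher and 6508 lower, and fitting these IDs alone, with their own scaling, gave 3418 higher and 3655 lower. The median log2 fold change of these 15436 IDs was -1.15 in the fit of all IDs and -0.03 when they were fitted alone.

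The number of higher calls moved with the libraries and the design of the fit. With the construct as a block, 8289 IDs were higher and 5379 lower. Without RIP variant 1 only 938 IDs were higher and without RIP variant 2 only 1082, while the lower calls numbered 5339 and 5275. Scaling on library totals in place of TMM moved the median log2 fold change of the 15436 IDs to 0.05 and gave 24271 higher and 3213 lower calls (88.3% higher).

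The folds of single IDs depend on TMM scaling. Among the higher IDs, ENSG00000272168 had the largest fold change that met the count rule. It had 170 CPM (95% exact Poisson interval 157 to 184) in RIP variant 1 and 192 CPM (180 to 204) in RIP variant 2, from 667 and 998.5 counts, with 0 counts in both inputs. It was at least 1262-fold higher in RIP for variant 1 and at least 1667-fold for variant 2 (edgeR adjusted p = 0.00060). ENSG00000078295 had 171 and 145 CPM in the RIP libraries and 0 counts in the inputs, which is at least 1268-fold and at least 1258-fold higher (edgeR adjusted p = 0.00060). Among the lower IDs, ENSG00000178531 had 23.5 and 41.1 CPM in the inputs of variants 1 and 2 and 0 counts in both RIP libraries, so it was at least 69.6-fold and at least 161-fold lower in RIP (edgeR adjusted p = 0.0014). ENSG00000206634 had 21.5 and 30.2 CPM in the inputs and 0 counts in both RIP libraries, which is at least 63.6-fold and at least 118-fold lower (edgeR adjusted p = 0.0016). On library totals, the bounds were lower for these IDs, at 30.7-fold and 71.4-fold for ENSG00000178531 and 28.1-fold and 52.4-fold for ENSG00000206634 (variants 1 and 2), and higher for the IDs enriched in RIP, at 2835-fold to 3756-fold. If each fragment was counted as 2 reads, a 0 allows 6 reads and each bound is 2 times lower, so that the smallest for the lower IDs was 14.0-fold on library totals and the smallest for the higher IDs 629-fold on TMM scaling.

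Each variant was also compared with its own input, without a test because each side is 1 library. For variant 1, 26272 IDs were at least 2-fold higher in RIP than in its input and 9598 at least 2-fold lower. For variant 2 the numbers were 26817 and 8831. These numbers depend on TMM scaling. On library totals, 29284 IDs were higher and 5922 lower for variant 1, and 30108 and 4840 for variant 2. The log2 ratios of the constructs, which share no library, had a Pearson correlation of 0.83 and a Spearman correlation of 0.81 across the 41622 IDs. Genes are not independent replicates. The inputs were alike (Pearson correlation of log2 counts 0.93 across all IDs), so the ratios have similar denominators. RIP levels that vary little between IDs would then also give a high correlation and shared signs. The agreement of the ratios therefore does not show that both variants captured the same RNAs. The sign was the same for 90.6% of the IDs, a share that includes IDs at 0 in both inputs, whose ratio cannot be negative. It was 85.2% (95% exact binomial interval 84.7% to 85.7%) over the 21738 IDs with a count in both inputs, where the Pearson correlation was 0.79. At least 2-fold higher in both were 24646 IDs, at least 2-fold lower in both 7223, and 1040 were at least 2-fold higher in one and 2-fold lower in the other. Only 234 of the latter remained among 22939 IDs with at least 50 counts in the higher library of each construct.

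**Figure D3:**
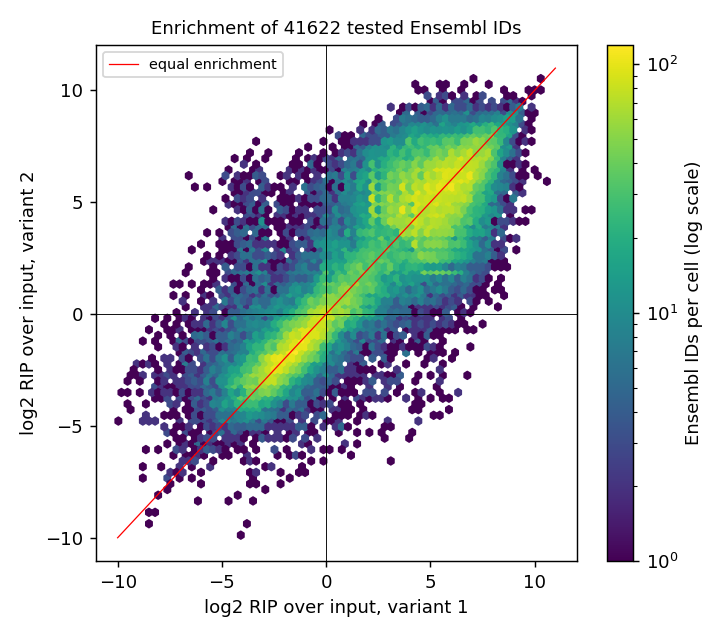
Log2 ratio of RIP over input for SRP9 variant 1 (horizontal axis) and variant 2 (vertical axis) over 41622 tested Ensembl IDs, drawn as hexagonal cells coloured by the number of IDs on a log scale; the red line marks equal ratios. Most IDs (90.6%) have the same sign in both, with a Pearson correlation of 0.83 across IDs, including those at 0 in both inputs. The inputs were alike, so this agreement does not by itself show capture of the same RNAs.

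The RIP libraries of the variants differed from each other, at single-library resolution. At least 2-fold higher in RIP variant 1 than in RIP variant 2 were 7793 IDs, and 9489 were at least 2-fold lower. Among 26368 IDs with at least 50 counts in the higher of both libraries the numbers were 3963 and 5055. The inputs of the variants differed too. Of 18840 IDs with at least 50 counts in the higher input, 1953 were at least 2-fold higher and 2023 at least 2-fold lower in variant 1. Over the 14827 IDs with at least 50 counts in both the higher RIP and the higher input, 1722 were at least 2-fold higher and 2336 at least 2-fold lower in RIP variant 1, and 1353 and 1265 in its input. Over the same IDs the log2 difference had a median absolute deviation, scaled to an SD, of 0.86 between the RIP libraries and 0.43 between the inputs, while its SD was 1.20 and 1.26, so the order depends on the measure there. Over the 15436 IDs with at least 50 counts in both inputs, both measures were larger between the RIP libraries, at 0.91 and 0.38 for the former and 1.36 and 0.53 for the SD. Over the 21738 IDs with a count in both inputs they were 1.01 and 0.55, and 1.56 and 1.05. Both of these sets put a minimum on the inputs only, which limits the input difference while a RIP value may be 0. The RIP libraries were also shallower, so the wider spread between them cannot be read as a difference between the variants. Taking the inputs into account, the enrichment was at least 2-fold larger with variant 1 for 4182 IDs and at least 2-fold larger with variant 2 for 5590, among the 22939 IDs with at least 50 counts. No difference between the variants has a replicate check.

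The IDs furthest apart between the RIP libraries were at 0 counts in one of them. ENSG00000267801 had 96 counts (24.5 CPM, 95% exact Poisson interval 19.8 to 29.9) in RIP variant 1 and 0 in RIP variant 2, at least 43.0-fold higher with variant 1, and its inputs had 5.77 and 3.26 CPM. ENSG00000223497 had 76 counts (19.4 CPM) and 0, at least 34.0-fold higher with variant 1, with 1.07 CPM in the input of variant 1 and 0 counts in that of variant 2. ENSG00000128268 had 184 counts (35.3 CPM) in RIP variant 2 and 0 in RIP variant 1, at least 45.7-fold higher with variant 2, and its inputs had 8.86 and 6.43 CPM for variants 1 and 2. ENSG00000118508 had 164 counts (31.5 CPM) in RIP variant 2 and 0 in RIP variant 1, at least 40.7-fold higher with variant 2, and its inputs had 26.1 and 31.1 CPM. Library totals gave bounds of 33.7-fold to 46.2-fold for these 4 IDs, and with 6 reads for a 0 these became 16.8-fold to 23.1-fold. Among 8004 IDs with 20 to 39 counts in RIP variant 2, 19.1% were at 0 in RIP variant 1, and among 7443 IDs with 20 to 39 counts in RIP variant 1, 4.14% were at 0 in RIP variant 2. Among 2404 IDs with 20 to 39 counts in the input of variant 2, 30.0% were at 0 in the other input. Among 2787 in the input of variant 1, 36.2% were. The same count is a lower CPM in the deeper inputs, so these shares are not at equal levels. The 4 named IDs have higher counts, where a 0 was rarer. At 80 to under 160 counts, 1.00% of 8564 IDs in RIP variant 2 were at 0 in RIP variant 1. In the other direction it was 0.092% of 7633 IDs, and 1.53% of 8245 at 40 to under 80 counts. In the inputs at 80 to under 160 counts, 6.64% (variant 2) and 6.13% (variant 1) were at 0 in the other.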

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

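All tests in this part were chosen after the result was seen. Of the 4 IDs named for RIP variant 1 against RIP variant 2, RIP over input went opposite ways with the variants for 2. Over all tested IDs, 1040 were at least 2-fold higher in RIP with one variant and at least 2-fold lower with the other. The difference was not tested, as each value rests on 1 library. For ENSG00000267801 the log2 ratio of RIP over input was 0.90 with variant 1 and -5.75 with variant 2, a difference of 6.64. For ENSG00000128268 it was -7.19 with variant 1 and 1.28 with variant 2, a difference of -8.47. Both have 0 counts in 1 RIP library, so the sizes depend on the prior count.

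Part of the IDs with 20 to 39 counts in one RIP library were at 0 in the other, more often in one direction. Of IDs with 20 to 39 counts in RIP variant 2, 19.1% were at 0 in RIP variant 1 (95% exact interval 18.2% to 19.98%), and of those with 20 to 39 counts in RIP variant 1, 4.14% were at 0 in RIP variant 2 (3.70% to 4.62%). At 40 to under 80 counts these shares were 7.33% and 1.53%, and at 80 to under 160 counts 1.00% and 0.092%. RIP variant 2 also had more total counts, and detected more IDs after thinning (50897 against 44416). If levels were equal, Poisson counting error at these depths would leave far smaller shares at 0. At 20 to 39 counts they would be 3.3e-06% in RIP variant 1 and 2.4e-11% in RIP variant 2. With fragments of 2 reads they would be 0.010% and 2.1e-05%. A candidate explanation for the IDs at 0 is that few independent molecules stand behind the reads, as after strong amplification of little RNA. In the inputs 30.0% of IDs with 20 to 39 counts with variant 2 were at 0 with variant 1, which also fits real differences between the transfected cells. Few molecules behind the reads and binding to only 1 of the variants cannot be told apart without a repeat library. The correlation of the RIP difference with the input difference (-0.0045 across tested IDs) cannot decide it. Of those IDs, 12812 were at 0 in both inputs and have no input difference.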

How the results depend on the processing

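Halved counts, whole-valued IDs, the limits on input counts, the shared ID sets and thinning for the test were chosen after seeing the data. In the test of RIP against input, the higher calls (20595) and lower calls (6583) stayed within 1.5 times the main count under DESeq2 size factors, no filter, the DESeq2 Wald test, limma-voom, halved counts and thinning, and 0 calls turned direction under any alternative. The higher calls fell to 8289 with the construct as replicate block (8246 of them among the main calls), to 8195 with at least 50 counts in 2 or more libraries, and to 4522 for IDs with a count in an input. The lower calls fell to 3213 with library totals and to 3253 for whole-valued IDs. For the 15436 IDs with at least 50 counts in both inputs, fitting them alone gave 3418 higher and 3655 lower calls, against 1282 and 6508 in the fit of all IDs, with 1282 and 3655 shared. Leaving out 1 library gave 938 to 18394 higher calls, with the lowest values without a RIP library (938 without variant 1, 1082 without variant 2). The lone library is then assumed to vary like the other fraction. Lower calls stayed between 5275 and 6452. The filters test fewer IDs, and otherwise the cause was not tested. The IDs named for RIP against input kept their direction and their calls wherever they were tested. Those named between the RIP libraries kept their direction but not their size (7.48 to 5.38 thinned and 9.47 with prior 0.5 for ENSG00000267801), and ENSG00000223497 was not tested after thinning.

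For single libraries, counts of IDs at least 2-fold apart moved as follows. With library totals, IDs lower in RIP numbered 5922 for variant 1 and 4840 for variant 2, and the share of IDs with the same sign was 89.8%. With at least 50 counts in the higher library, IDs higher in RIP numbered 11790 and 14102 for variants 1 and 2, those between the RIP libraries 3963 and 5055 (higher and lower with variant 1), those of the enrichment difference 4182 and 5590, and those between the inputs 1953 and 2023. With thinning, IDs lower in RIP numbered 6037 and 5832, those between the RIP libraries 4440 and 5069, those of the enrichment difference 5680 and 6710, and those between the inputs 2827 and 2331, and the same-sign share was 92.4%. That share was 85.2% for IDs with a count in both inputs and 86.3% for those with at least 50 counts in both. For IDs with at least 50 counts in the higher RIP and the higher input, 1722 and 2336 were 2-fold apart between the RIP libraries and 1353 and 1265 between the inputs. DESeq2 size factors and a prior count of 0.5 kept every count within 1.5 times. The alternatives that need gene names were not run. RIP depth limits what a 0 means, since 3 counts are 0.765 CPM in RIP variant 1 and 0.576 CPM in RIP variant 2.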

Other observations

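All tests in this part were chosen after the result was seen. IDs without a count in either input held 15.0% and 15.3% of the RIP counts. Sequencing depth is argued against, since the inputs, which hold more counts, detected at most 28372 IDs against 44658 in the RIP library with fewer IDs. Division of reads between IDs was not settled. Those of the IDs with whole values in both RIP libraries held 12.2% of the counts of RIP variant 1. Parts of divided reads can add up to a whole value, so this share cannot decide it. Genomic DNA carried into the RIP libraries may give such a floor, and so may capture of RNAs too rare for the input. These cannot be told apart here, because both predict that the same IDs recur in both RIP libraries (Spearman correlation 0.64 over these IDs, 52.7% of them with a count in both), no ID lengths were used here, and no precipitation without a tagged SRP9 was analysed here.

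Even counts outnumbered odd counts in every library. Among whole values under 40, 53.4% and 51.5% were even in RIP variants 1 and 2, and 60.9% and 62.1% in the inputs, with the lower end of the lowest exact interval at 50.9%. Each of the 19 even values from 2 on was more frequent than the mean of its odd neighbours in all 4 libraries. The cause was not tested, and counting of both reads of a fragment was not excluded. With fragments of 2 reads, the interval of ENSG00000272168 in RIP variant 1 is 152 to 189 CPM in place of 157 to 184 CPM, and each lower bound on a fold is 2 times lower. Halving the counts gave 19165 higher and 6868 lower calls in RIP against input.

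Other groupings of the 4 libraries called no ID with edgeR at an adjusted p under 0.05. Splitting by construct called 0 (0 at an unadjusted p under 0.05), the crossed split 0 (1 unadjusted), and the construct with the fraction as a term 0 (114 unadjusted). In the split by construct and the crossed split, each group held a RIP and an input library. The RIP against input difference counted as error there, and the 0 calls of these splits say nothing about chance. The fit with the fraction as a term has 1 residual degree of freedom. Its 114 of 41622 IDs lie well below the share of 0.05 given by chance. Its 0 calls are thus no evidence that the variants are alike. With 4 libraries the splits are also too few to judge chance. RIP libraries correlated with each other (Spearman 0.81 across all IDs) less than the inputs with each other (0.85), and RIP with its own input at 0.55 for variant 1 and 0.54 for variant 2. With the input of the other variant the values were 0.52 for RIP variant 1 and 0.57 for RIP variant 2. Both RIP libraries were thus closer to the input of variant 1 than to that of variant 2.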
